A study of Rhodoluna lacicola with 8 samples.

How the data were processed

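The data were 8 strand-specific RNA sequencing libraries of *Rhodoluna lacicola* strain MWH-Ta8, 4 from cultures in constant light and 4 from cultures in constant darkness. Per the labels' protocols, cultures of 50 mL were grown in NSY medium at 6 g per litre, light came from a 13 W compact fluorescent lamp, and RNA was depleted of rRNA, fragmented, converted with a TruSeq stranded kit, and size-selected for short fragments. The groups and replicate numbers were taken from the sample titles, and the labels describe the replicates as separate cultures. A second strain named in the series' design text was not analysed here.

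The authors deposited 1 table per library with gene-level FPKM and the lower and upper bounds of its confidence interval, per the file headers, which are those of a Cufflinks tracking table. The submitters' processing notes name Trim Galore 0.4.1, cutadapt 1.12, FastQC, TopHat, Cufflinks and Cuffdiff, without roles or parameters. Which fragments entered the library total behind the FPKM, and whether strand was used in counting, are not given in the sources used here. Each table lists 1406 loci by locus tag and coordinates on the reference sequence CP007490.1, whose last listed base is 1430111. Coordinates are given 1-based. Of the tested loci, 99.9% had a length that is a multiple of 3, so lengths are coding lengths. Neighbouring loci overlapped in 309 cases, by at most 90 nt, and fragments in an overlap cannot be assigned to 1 gene. The tables give no symbols, products or strand, and no annotation was used here. The 26 gene lists fixed before the data were examined, among them photoreceptors and pigment synthesis, therefore matched 0 loci and their tests were void. The rule for named genes then allowed at most 2 locus tags in each direction, those with the largest change among called genes whose light and dark values do not overlap. It also took the up to 4 longest runs in each direction, given here by coordinates; the fourth place was tied in gene number in both directions, and the tied runs were included, which made 5 each way. It further took the 5 loci with the highest mean.

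FPKM are not counts, so no count model was used. Each library was multiplied by a median-of-ratios factor over the tested genes, between 0.810 and 1.27, because FPKM of all genes shift when a few abundant RNAs take a different share of the fragments. Such scaling sets the median gene near 0 change, so directions are relative to that gene. Values were tested as log2(scaled FPKM + 1), and fold changes on this scale understate the change of low genes. Left out of the test were 49 loci under 150 nt, for which the length correction is unstable, 2 loci whose estimate failed in at least 1 library and is listed as 0 there, and 8 loci with a mean scaled FPKM below 10. Loci of rRNA or tRNA could not be recognised without an annotation.

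Light and dark were compared with limma 3.58.1 in R 4.3.3 (linear model with group as its only term, moderated statistics with a variance trend, two-sided, Benjamini-Hochberg adjusted p below 0.05). Single values per library were compared by exact permutation tests over all 35 splits of 8 libraries into 4 and 4, whose smallest two-sided p is 0.0286. Runs were 3 or more neighbouring tested genes called in the same direction, and were compared with 1000 seeded random placements of the calls. The level of a run in a library is the geometric mean of its genes. The model was tested on simulated data for the 1347 genes. It recovered 78% of genes changed by 1.5-fold, 94% of those changed by 2-fold and 100% of those changed by 3-fold or 4-fold, and 11 of 1147 unchanged genes were called, which made up 5.58% of the calls. The simulated changes were balanced between the directions, 50 genes at each fold, with noise independent between genes. Scaling and false calls were therefore not tested for changes as many and as unbalanced as in the data.

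The depth was estimated by taking the deposited interval as the estimate plus or minus 2 standard deviations of a count. For loci under 150 nt with fewer than 30 implied fragments, most of the implied numbers were whole within 0.1. The estimate was 11200000 to 16800000 fragments per library, lowest in light 4, and the median half-width of the interval was 4.26 to 4.87% of the value. These intervals cover counting error only. No values were identical between libraries, and replicates differed by more than counting error, with a median squared standardised difference of 2.15 to 26.1 within groups against 0.455 from counting error alone, so each library was used as 1 replicate. Alternatives covered library scaling, the pseudocount, filters on level, length and status, the variance model, library weights, the replicate number as a block, thresholds, run length, and leaving out each library.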

Results

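Transcript levels were measured by RNA sequencing in *Rhodoluna lacicola* strain MWH-Ta8, a freshwater actinobacterium that does not grow phototrophically. Of the 8 cultures, 4 were kept under constant light from a fluorescent lamp, at 30 to 40 µmol photons m-2 s-1, and 4 in constant darkness. Each culture was harvested late in exponential growth and gave 1 library. The comparison of the 2 groups asked which transcripts differed between growth in light and growth in darkness. The deposited tables held FPKM (fragments per kilobase of gene, relative to the mapped fragments of the library) for 1406 loci on the reference sequence CP007490.1, and 1347 of these loci were tested. The tables held no read counts. From the width of the deposited confidence intervals, an estimated 11200000 to 16800000 fragments stood behind each library, with a mean of 14400000 ± 2300000 in light and 14300000 ± 1000000 in darkness (SD, n = 4). The files paired locus tags with no gene symbols or products. Most results are therefore given for chromosomal regions, and 2 loci are named in each direction.

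Transcript levels differed between light-grown and dark-grown cultures at 775 of the 1347 tested genes, or 57.5%. In light, 378 genes were higher and 397 were lower, and 572 did not pass the test (limma, Benjamini-Hochberg adjusted p below 0.05). Both directions were spread over the whole chromosome. The genes lower in light had the larger changes, with a median log2 fold change of -0.88 against 0.40 for the genes higher in light. A change of 2-fold or more was found for 175 genes that were lower in light and 30 that were higher, and a change of 4-fold or more for 36 and 9 genes. The change was under 1.5-fold for 436 of the 775 called genes. The 4 light values and the 4 dark values did not overlap for 729 genes, or 54.1% of those tested, against 2.86% by chance. These directions were relative to the median gene. With FPKM as deposited 683 genes were higher and 222 lower, and with scaling to the library total 976 were higher and 176 lower. At 2-fold or more the split was then 82 and 82 genes as deposited, and 198 higher and 59 lower with scaling to the total. As deposited, the median FPKM was 424 in dark 1 and 299.98 to 318 in the other dark libraries. Without scaling this offset enters the spread of most genes alike, so the counts as deposited are less reliable.

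**Figure D1:**
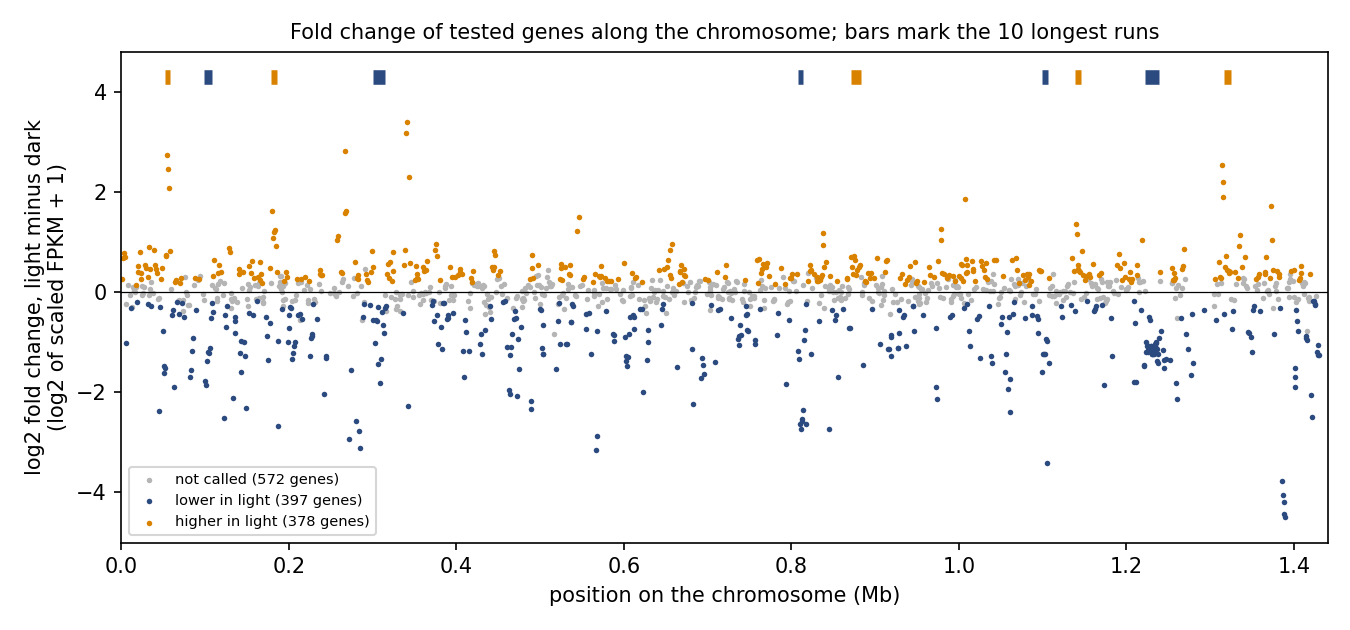
Log2 fold change of each tested gene (light minus dark, on the log2 scale of scaled FPKM + 1) against its position in Mb; orange points were higher in light, blue points lower and grey points not called, and the bars at the top mark the 10 longest runs, 5 in each direction. The 378 genes higher in light and the 397 genes lower in light lie along the whole chromosome, and the lowest points reach -4.48.

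The steepest difference lay between positions 1384845 and 1390768, where 5 adjacent genes were 18.2-fold higher in darkness. The level of this region, taken as the geometric mean of its genes, was 164 ± 53.8 scaled FPKM in light and 3063 ± 1107 in darkness (SD, n = 4). Within it, Rhola_00013610 (1388927 to 1390768) had 371 ± 143 scaled FPKM in light and 8558 ± 3580 in darkness, a log2 fold change of -4.48 ± 0.44 (SE; limma adjusted p = 4.17e-05). Its neighbour Rhola_00013600 (1388370 to 1388927) changed by -4.42 ± 0.40 on the log2 scale (adjusted p = 2.43e-05), from 7315 ± 2805 in darkness to 333 ± 120 in light. These 2 loci overlap by 1 nt. The dark values of the region were uneven, at 1411 in dark 4 against 3464 to 3702 in the other dark libraries, and every one of them lay above the highest light value of 207.

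A second region with a large difference ran from 807187 to 813742. Its 7 genes were 4.56-fold higher in darkness, at 2421 ± 77.0 scaled FPKM against 533 ± 57.4 in light (SD, n = 4), and the least changed of them had a log2 fold change of -1.17. The longest run of genes lower in light held 29 neighbours between 1222645 and 1239350, with a mean log2 fold change of -1.11 and a range from -1.42 to -0.51. Its level was 2162 ± 905 scaled FPKM in light and 4399 ± 172 in darkness. Light 4 stood apart in this run at 3484, against 1470 to 1975 in the other light libraries, and remained below the lowest dark value of 4225. Without light 4 the mean log2 fold change was -1.36. With quantile normalization it was -0.49, and 13 of the 29 genes passed the test. The next longest run, of 12 genes from 300214 to 314310, changed by a mean of -0.82 (272 ± 22.1 against 479 ± 22.4 scaled FPKM). With scaling to the library total its mean change was -0.21 and 4 of its 12 genes were called. A run of 8 genes from 99129 to 108450 changed by a mean of -1.16, from 194 ± 26.2 scaled FPKM in darkness to 88.0 ± 23.4 in light. The 7 genes from 1098552 to 1106243, as many as in the run from 807187, were 2.87-fold higher in darkness (256 ± 4.41 against 89.0 ± 5.41).

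Among the genes higher in light, the changes were largest at Rhola_00003310 (339679 to 341463) and at the neighbouring Rhola_00003300 (339353 to 339679), which overlap by 1 nt. Rhola_00003310 had 829 ± 268 scaled FPKM in light and 76.1 ± 11.1 in darkness (SD, n = 4), a log2 fold change of 3.38 ± 0.22 (SE; limma adjusted p = 3.19e-06). Rhola_00003300 had 3213 ± 1201 scaled FPKM in light and 342 ± 77.2 in darkness, a log2 fold change of 3.17 ± 0.28 (adjusted p = 2.07e-05). All 4 light values were above all 4 dark values at both loci.

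The 5 longest runs of genes higher in light held 9 genes in 1 case and 6 in the other 4. The longest, with 9 genes from 870717 to 882783, had a modest mean log2 fold change of 0.53 (177 ± 21.1 scaled FPKM in light, 122 ± 6.96 in darkness; SD, n = 4). With scaling to the library total its mean log2 fold change was 1.13. The run of 6 genes from 52549 to 58395 was 3.01-fold higher in light, at 268 ± 48.0 against 87.1 ± 4.50 scaled FPKM. The 6 genes from 179127 to 186165 were 2.11-fold higher in light (168 ± 31.4 against 78.1 ± 3.12), and those from 1138891 to 1145117 were 1.65-fold higher (234 ± 30.8 against 141 ± 13.7). The 6 genes from 1316287 to 1324323 were 1.39-fold higher (429 ± 29.8 against 308 ± 9.58). Runs in which each gene changed by 2-fold or more were picked out after the values were seen, among them the region from 1384845 to 1390768. Higher in light were 3 genes from 54066 to 57207, inside the run from 52549, by 5.34-fold (175 ± 45.7 against 31.1 ± 2.53 scaled FPKM), 3 genes from 1313619 to 1315687 by 4.63-fold (2949 ± 1139 against 597 ± 63.7), 3 genes from 265957 to 269072 by 4.03-fold (430 ± 114 against 103 ± 3.63), and 4 genes from 179127 to 183778, inside the run from 179127, by 2.43-fold (146 ± 32.2 against 58.2 ± 3.04). From 1313619 to 1315687 light 4 had 1477 scaled FPKM and the other light libraries 2932 to 4248. For each region named above, the 4 light and the 4 dark levels did not overlap (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 allows). The regions were selected by the same test, so this p is a description. None of them changed direction under any scaling, but this was likely in any case. The other scalings moved the median gene upward, by at most 0.61 on the log2 scale. Among the regions lower in light, the smallest mean change was -0.82.

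**Figure D2:**
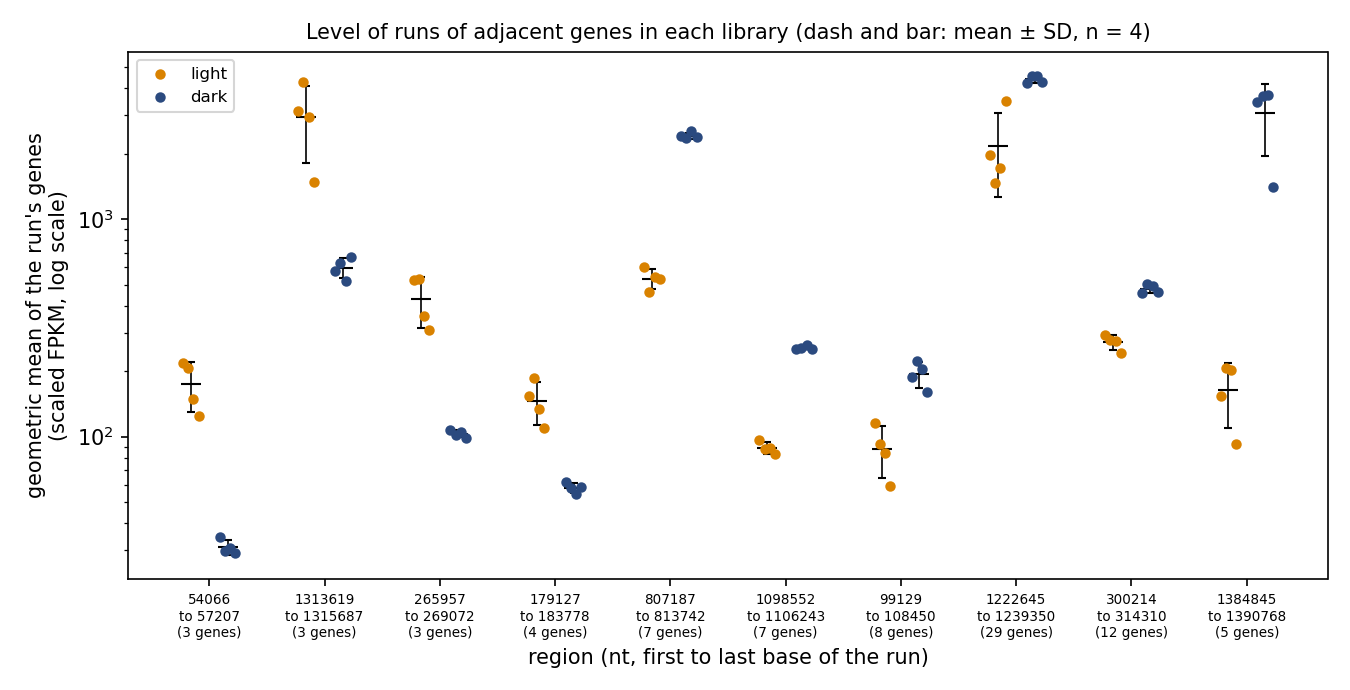
Level of 10 runs of adjacent genes in each library (geometric mean of the run's genes, scaled FPKM, log axis; orange light, blue dark; dash and bar, mean ± SD, n = 4), with 4 runs higher in light on the left and 6 lower in light on the right. Light and dark libraries do not overlap in any of the 10 runs, and the separation is widest from 1384845 to 1390768, at 164 against 3063.

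Of the 5 loci with the highest mean, 2 were in the limma test, and 1 of these was higher in darkness. Another 2 are under 150 nt, outside that test, and were higher in darkness by unadjusted exact permutation tests only. The last had a failed estimate and was not tested. Of the 5, 4 are 73 to 279 nt long, where a level in FPKM depends on the length correction. The locus with the highest mean, from 1225455 to 1225568, lies within the run of 29 genes and is 114 nt long, below the length tested. It had 68525 ± 18675 scaled FPKM in light and 138403 ± 8858 in darkness (exact permutation p = 0.0286, n = 4). With scaling to the library total this difference was 1.34-fold and the ranges of the groups overlapped. The 73-nt locus from 663864 to 663936 had 34609 ± 7886 in light and 89496 ± 10346 in darkness, with the same exact permutation p of 0.0286. Of the 2 tested loci among the 5 most abundant, that from 1401126 to 1401296 was 3.60-fold higher in darkness (18215 ± 5117 against 65589 ± 1240 scaled FPKM; limma adjusted p = 4.93e-05). The other, from 1400071 to 1400349, was not distinguishable between the groups at 62072 ± 13296 and 66272 ± 12476 (adjusted p = 0.707), and with scaling to the library total its dark mean was 0.694 times its light mean. The locus from 1206751 to 1208007 had a failed estimate in dark 1 and was not tested. Its scaled FPKM ranged from 37164 to 45978 in the 4 light libraries and from 62836 to 69095 in the other 3 dark libraries. This difference depended on the scaling: with scaling to the library total the ranges overlapped, from 49080 to 56754 in light and from 50414 to 55165 in darkness. The 10 most abundant tested genes took 17.6 ± 0.67% of the summed FPKM of tested genes in light and 21.6 ± 1.26% in darkness, and the 50 most abundant took 41.7 ± 1.43% and 49.2 ± 1.22% (exact permutation p = 0.0286 for each; adjusted p = 0.0629 over 11 library measures, n = 4). Weighted by gene length, the share of the 50 was 24.4 ± 1.11% in light and 28.8 ± 1.05% in darkness.

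**Figure D3:**
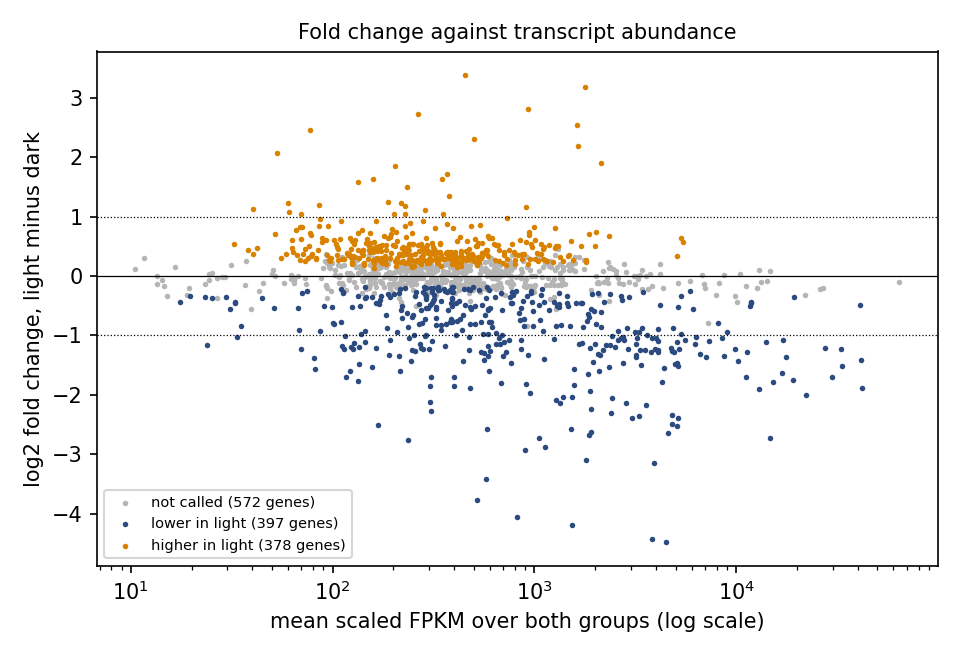
Log2 fold change (light minus dark) of each tested gene against its mean scaled FPKM over both groups on a log axis, with dotted lines at 2-fold and colours as in the plot along the chromosome. Most of the 175 genes lower in light by 2-fold or more lie at the abundant end, and the 30 genes higher by as much lie mainly at lower abundance.

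Changed genes sat next to each other. Of the 775 called genes, 445 lay in runs of 3 or more neighbours called in the same direction, 192 of them in 49 runs higher in light and 253 in 54 runs lower in light. Random placement of the calls among the tested genes gave a median of 155 such genes and at most 218 (permutation p = 0.001, the smallest that 1000 shuffles can give). Calls of 2-fold or more formed 19 runs lower in light with 89 genes and 4 runs higher in light with 13 genes, where shuffling gave a median of 7 genes in all. The files do not say which neighbours lie on 1 transcript, so neighbours were not taken as independent measurements. The files give no strand, and runs could not be limited to genes read in the same direction.

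The libraries separated by growth condition. The first principal component held 84.4% of the variance and parted the 4 light libraries, with scores from 10.97 to 17.3, from the 4 dark libraries, with scores from -15.9 to -12.2. Pearson correlations of log2 values across genes were 0.965 to 0.995 among light libraries, 0.992 to 0.998 among dark libraries and 0.895 to 0.939 between the groups. Distances between the groups exceeded those within them by more than in any other split of the 8 libraries (exact permutation p = 0.0286, the smallest that 35 splits allow). The second component, with 9.89% of the variance, set light 4 apart at -11.9 from the other light libraries at 2.35 to 4.84.

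**Figure D4:**
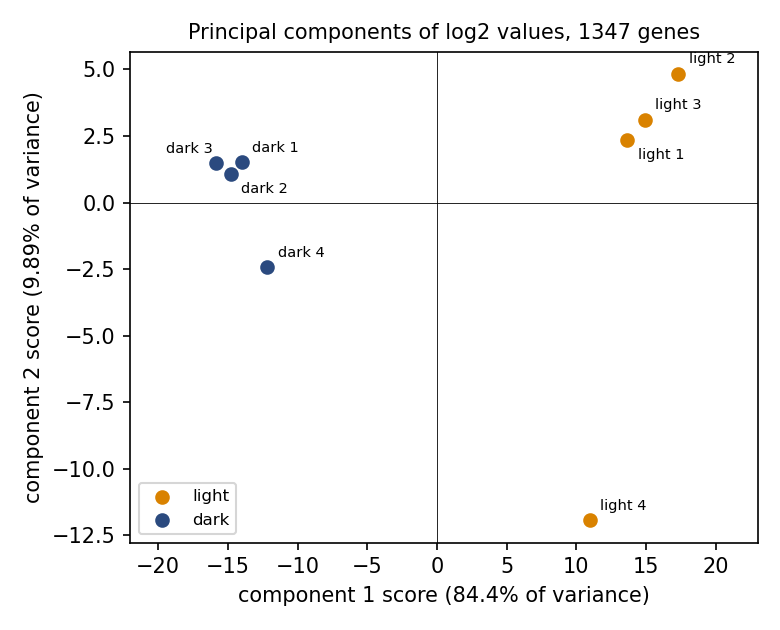
Scores of the 8 libraries on the first (84.4% of variance) and second (9.89%) principal components of log2 values of the tested genes, orange for light and blue for dark. Light and dark libraries lie on opposite sides of the first component, and light 4 lies alone at -11.9 on the second.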

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

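The tests of depth and of dark RNA for light 4 were settled only after related results had been seen. Each value was compared with the others of its group of 4. In 6 of 62 such comparisons a library lay far from the other 3, where chance gives about 3.1. Some comparisons overlap, such as a region and a gene within it, so 6 against 3.1 is a description and not a test. Light 4 lay apart on the second principal component, at -11.9 against 2.35 to 4.84 in the other light libraries, and in the summed scaled FPKM of loci under 150 nt, at 421920 against 291455 to 305182. Dark 4 lay apart on the same component at -2.42, against 1.08 to 1.51 in the other dark libraries. In the region from 1384845 to 1390768 dark 4 had 1411 scaled FPKM against 3464 to 3702, and at Rhola_00013600 within it 3119 against 8430 to 8960. The median FPKM as deposited was 424 in dark 1 and 299.98 to 318 in the other dark libraries.

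Light 4 differed from the mean of the other light libraries by over 1 log2 unit at 71 genes, higher at 51 and lower at 20. It lay toward the dark level at 71.3% of 230 genes, as in the run of 29 genes. These 230 genes differed by 2-fold or more between the other light libraries and the dark ones. The same share for each of the other light libraries, taken in the same way, was 21.5 to 49.0%. Their reference mean included light 4, which may lower these shares, so they are not an independent baseline. Lower depth does not account for the deviation of light 4. Light 4 had the lowest estimated depth at 11200000 fragments, but among the most abundant 25% of genes its median deviation was 0.32 log2 units, 2.06 times the largest of the other light libraries and 15.2 times the counting error. An admixture of dark RNA large enough to account for this is argued against as well. The 6 genes at least 8-fold higher in darkness than in the other light libraries allow a median share of at most 3.37%, and no more than 6.01% for any of them. Over the 230 genes the median share needed was 25.2%, with quartiles of -2.79 and 57.2%. The 51 raised genes need a median of 78.9%, but were selected for being raised. The limit rests on few genes. They include the neighbours Rhola_00013610 and Rhola_00013600, where light 4 and dark 4 were the lowest of their groups. A difference in fragment length stays open. Deviation and gene length were nearly unrelated across the tested genes, with a Spearman correlation of -0.071. The tested genes leave out loci under 150 nt, for which the length correction is unstable. In light 4 the summed scaled FPKM of those loci was raised, at 421920 against 291455 to 305182 in the other light libraries. This sum was higher still in the dark libraries, at 518177 to 707670, so its rise does not decide the cause. A difference of that culture, such as its growth stage at harvest, also stays open. For this the labels give no value per culture, and no test was possible.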

How the results depend on the processing

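Scaling to the library total without the 50 most abundant genes, and the naming of 2-fold runs, were chosen after seeing the data. The number of called genes depended on library scaling, which moved the median log2 fold change of all genes from 0.00 to 0.40 as deposited, 0.61 with scaling to the library total, 0.41 with that total without the 50 most abundant genes, 0.17 with upper-quartile scaling and 0.12 with quantile normalization. Against 378 higher and 397 lower, the calls were 683 and 222, 976 and 176, 866 and 236, 619 and 312, and 516 and 292 in that order, and genes in runs were 535 and 134, 927 and 84, 779 and 145, 467 higher with upper-quartile scaling, and 297 and 154 with quantile normalization, against 192 and 253. The total turned 67 of the 775 calls to the other direction, the total without 50 genes 15 and quantile normalization 8. The shift of the median by these scalings is by construction. At 2-fold or more, 30 genes were higher and 175 lower, with 13 and 89 in runs. Genes higher in light in runs numbered 300 with library weights, 111 at an adjusted p below 0.01, and 120 in runs of 4 or more; the cause was not tested for the weights. Leaving out each library gave 329 to 464 genes higher and 359 to 456 lower, both highest without light 4. The replicate numbers showed no consistent pairing of the cultures: deviations of same-numbered libraries correlated at -0.245, 0.021, 0.0034 and 0.288. Only 1 of 4 numbers, replicate 4, correlated best with itself, and a difference shared by its light and dark cultures is not excluded. With the replicate block 371 genes were higher and 393 lower, and on replicates 2 to 4, 267 and 320, with 110 higher in runs. All other counts of called genes and of genes in runs stayed within 1.5 times. Counts at 2-fold or more also moved with scaling. They were 41 higher and 108 lower with quantile normalization, and 88 and 81 with the total without the 50 most abundant genes. Of 567 values of the 4 named loci and 17 regions under the alternatives, none reversed and 558 kept their call. In the other 9, fewer of a region's genes were called than not. The loci and regions were chosen for long runs or large changes, so reversals under other scalings were unlikely in any case. Tests of gene lists and light-sensing genes were not run, since no locus could be matched. Simulation recovered 78% of 1.5-fold changes; how much of this depth limits was not tested, and replicates differed by more than counting error.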

Other observations

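The test of abundance for short genes, and the windows, classes and neighbouring pairs described first, were chosen only after the results had been seen. Relative to the median gene, abundant transcripts lay lower in light. In the most abundant 25% of tested genes 168 were lower in light and 47 higher, with a median log2 fold change of -0.32. This class held 100 of the 175 genes lower by 2-fold or more. It also held 69 of the 95 tested genes under 300 nt, so abundance and length cannot be told apart in it. Neighbouring genes changed together, so these counts are not of independent genes. In the least abundant 25% 67 genes were lower and 126 higher, with a median of 0.13. A single factor per library shifts both medians alike, so the difference between them does not rest on such scaling. Where each lies relative to 0 does, its direction included. With scaling to the library total the median of all genes moved to 0.61, a larger shift than the -0.32 of the most abundant 25%. Of the windows of 100000 nt, that from 1200001 to 1300000 stood out, with 51 of its 84 tested genes lower in light, 16 higher and a median of -0.81, and the medians of the other windows lay between -0.20 and 0.18. Outside the run of 29 genes, 5 neighbours from 1242306 to 1253438 also lay lower in light (2293 ± 997 against 5479 ± 308 scaled FPKM; SD, n = 4), with light 4 at 3748 and the other light libraries at 1556 to 2111. The 49 loci under 150 nt, when fitted with the other genes, gave 10 lower in light, 1 higher and 38 not called.

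Regions of opposite direction lay close together in places. The 3 genes from 50089 to 52461 were lower in light, at 67.4 ± 3.30 against 206 ± 63.1 scaled FPKM, directly before the run higher in light from 52549 to 58395. In the first of these dark 4 had 117 scaled FPKM, and the other dark libraries had 210 to 259. Such cases were a minority: of 496 neighbouring pairs with both genes called, 406 had the same direction and 90, or 18.1%, opposite directions, where shuffling the calls gave a median of 50.1% and no less than 41.7%.

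The split into light and dark was compared with the 34 other splits of the 8 libraries into 4 and 4. Only 1 of the 35 splits, the real one, gave as many as 775 called genes, and the highest of the others gave 0. This is a share of 1 in 35, the smallest these splits allow. The mixed splits carry the difference between light and dark in their residual spread, so low counts were likely there in any case. The splits therefore do not exclude chance by themselves. For the 445 genes in runs the splits decide nothing: again 1 of the 35 gave as many and the highest other gave 0, but a split without called genes has no runs.

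The shift of the median fold change with library scaling was weighed as a pattern. It would follow if a few genes took more of the summed FPKM in the dark libraries. The library total here is a sum of FPKM, so shares of fragments were not tested. With the 50 most abundant genes left out of the library total, the median log2 fold change under total scaling was 0.41 against 0.61 with them, or 67.7% of it, with a range of 66.5 to 69.8% when each library was left out, so these 50 genes alone do not account for it. Without the 200 most abundant it was 0.08, so the shift is carried by a wider set of abundant genes. Whether the 2 loci with failed estimates contribute stays open: in the 3 libraries where both are given, the median was 0.53 with them in the total and 0.54 without, but these are 2 light libraries and 1 dark. Whether cells in light held less of these transcripts or more of the others per cell stays open, since FPKM carry no absolute scale.

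Short genes lay lower in light than longer genes, the last pattern weighed. The 95 tested genes under 300 nt had a median log2 fold change of -0.32 and the 1252 longer genes 0.02 (permutation p = 1e-04, the smallest that 10000 shuffles can give, across genes that are not independent). The effective-length index of light libraries was 0.552% above that of dark libraries and their ranges overlapped. The length correction in the deposited values was thus alike in the groups. The index was taken from those values and their intervals, on loci under 150 nt against long genes. It cannot show a difference in fragment length that was left uncorrected, so such a difference stays open. A difference in abundance may contribute and cannot be told apart from length: after the median of each of 10 abundance classes was taken off, short genes differed by -0.11 (permutation p = 0.111 within classes), while within 4 abundance classes, from the least to the most abundant, they differed by -0.32, -0.14, -0.14 and -0.19, and 69 of the 95 lie in the most abundant 25%. No biological explanation was tested.

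Hypotheses on position along the chromosome were also tested. Neighbouring genes at most 50 nt apart had fold changes more alike than those over 200 nt apart, with an excess in Pearson's r of 0.476 against 0.296 at the 95th percentile of 10000 shuffles (permutation p = 0.0072, across gene pairs that are not independent), which is consistent with shared transcripts of closely spaced genes. The likeness was not limited to overlapping genes. The 602 pairs that do not overlap and lie at most 50 nt apart had an r of 0.676. It was 0.879 for 304 overlapping pairs and 0.178 for 339 pairs 51 to 200 nt apart. A fragment can reach across a gap of at most 50 nt and touch both genes. The 602 pairs therefore cannot exclude fragments shared by close neighbours. The 55 pairs over 200 nt apart had an r of 0.261. A gradual trend of fold change around the chromosome, as a difference in gene dosage would give, was not found: its amplitude was 0.026 log2 units, below the 95th percentile of 0.130 from 1000 shuffles of blocks of 20 genes (permutation p = 0.889).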
